A study of Mus musculus with 24 samples.

How the data were processed

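Liver RNA of male C57Bl/6J mice aged 8 weeks was measured on 1-colour Agilent expression arrays labelled with Cy3. The mice lacked Ppara in the liver (LKO) or did not (WT), and were fed freely or fasted for 24 h before they were killed at ZT16, that is, 16 h after lights on. The labels list 24 arrays from 22 animals, because 1 fed WT animal and 1 fasted WT animal were each hybridised on 2 arrays. The series description instead states 24 individual mice with 6 in each group. The animal numbers of the labels were followed, which gave 5 fed WT, 5 fasted WT, 6 fed LKO and 6 fasted LKO mice. The 2 arrays of an animal were averaged on the log2 scale before any test.

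Per the file headers, the scanner files hold fluorescence intensity values made with Agilent Feature Extraction 10.10.1.1, with background subtraction and spatial and multiplicative detrending, and no normalization between arrays. A small surrogate value replaces the processed signal of a spot not above background. The authors also deposited a table of log2 values, quantile normalized across arrays and made with limma per the labels, which holds 31356 probes. In that deposited table both arrays of a twice-hybridised animal carry the same averaged value. RNA amounts and RNA quality were measured by the authors before labelling, per the labels, and those quality values were not analysed here.

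The main values were the processed signals of the scanner files. Control spots and spots marked as outliers were left out, repeated spots of a probe were averaged, and log2 signals were set relative to the array's 75th percentile. That percentile ranged from 451 to 621.2 intensity units over the 24 arrays. The share of probes well above background ranged from 52.2% to 60.6%, and by group its mean was 56.0% ± 2.8 (SD, 6 arrays) in fed WT, 57.8% ± 1.5 in fasted WT, 57.0% ± 2.8 in fed LKO and 58.2% ± 1.8 in fasted LKO. Of 56605 probes, 46290 carried a gene symbol, and 28111 of these were well above background in at least 5 of the 22 animals, whatever their group. Each gene was represented by its kept probe with the highest mean level, which gave 17203 genes. Symbols are those of the array's design. Of 32993 probes whose transcript identifier was found in the reference table, 31459 had the same symbol there. Positions are in the mouse build mm9, as in the array files. The number of animals limits the precision of every value.

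A linear model with 1 mean per group was fitted to all 22 animals with limma 3.58.1 in R 4.3.3, followed by moderated tests and Benjamini-Hochberg adjustment over the 17203 genes. A gene was called at an adjusted p below 0.05. The 5 comparisons were fasting in WT, fasting in LKO, LKO against WT when fed, LKO against WT when fasted, and the difference of the fasting responses (the change in LKO minus the change in WT, the interaction term). Where no probe of a gene was well above background on any array of 1 group, the fold is given as a lower bound within the main processing: the brighter group's mean against, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background. That floor is not the detection limit of the gene's own probe. In the authors' deposited table every gene with such a bound below changed less than its bound. Examples are Bhlha15 with fasting in WT (-3.07, log2 bound 3.98) and Esrrg when fasted (-2.67, log2 bound 3.51).

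In all, 31 gene lists for liver pathways, programmes and cell types were fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives. The lists were tested with limma's camera, which compares a list with all other genes, using a correlation between genes estimated from the data and adjustment over the 31 lists of a comparison. Member counts are also given as adjusted over the list alone. The pathway lists cover mitochondrial, peroxisomal and omega-oxidation of fatty acids, ketone bodies, fatty acid uptake and lipid droplets, fatty acid synthesis, cholesterol, gluconeogenesis, amino acids, bile acids, xenobiotics, secreted factors, the unfolded protein and integrated stress responses, acute phase, autophagy, the cell cycle, the clock, sex-biased genes and the growth hormone axis. The cell type lists are markers of hepatocytes, endothelium, macrophages, stellate cells, lymphocytes, neutrophils, cholangiocytes, adipocytes, pancreas and red blood cells. Genes named in the text come from a panel of 24 genes, from the 10 genes with the largest change in each direction per comparison among called genes whose groups did not overlap (for the interaction, called genes without that condition), and from the 3 members with the largest change per list. Clone and predicted names were left out. Not every gene the rule allows is named, and the choice among them was made with the values in view. Some of these genes are not reported here, and the totals over named genes leave them out, among them a few whose calls changed under alternatives.

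The procedure was tested on simulated data drawn from each gene's mean and residual spread, with all groups at 1 mean and known changes added to some genes. Planted changes of 0.5 on the log2 scale were recovered for 41.8% to 64.2% of genes over the 5 comparisons, changes of 1 for 77.6% to 91.0%, and changes of 2 for 89.4% to 98.5%. Between 4 and 11 of the 17203 genes were called without a planted change. Each size was planted in 66 or 67 genes per comparison, and each gene was drawn independently of the others. In the data 681 to 8560 genes were called and genes are correlated. The simulated shares and false calls therefore do not give the recovery or the number of false calls in the data.

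Alternatives covered quantile normalization, normexp background correction with an offset of 50, unsubtracted median signals, the authors' deposited table, other filters and probe rules, slide and replicate number as blocks, single slides, single technical repeats, other variance models, stricter thresholds, the omission of each animal in turn, and 2 other list tests (camera with a preset correlation of 0.01, and fry). Technical repeats correlated at r = 0.9947 and 0.9934 across genes, which are not independent replicates, against 0.9811 to 0.9937 for different animals of a group. Each of the 3 slides held 2 arrays of every group. Probes without a gene symbol were left out because no gene could be assigned to them.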

Results

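The arrays measured liver RNA in 4 groups: 5 fed WT, 5 fasted WT, 6 fed LKO and 6 fasted LKO mice. WT stands for mice with Ppara in the liver and LKO for mice of the same strain with a liver-specific deletion of Ppara, which encodes a nuclear receptor that switches on genes of fatty acid use. Levels are log2 signals relative to each array's 75th percentile, and changes are log2 differences with their standard error (SE) from the fit to all 22 animals. On the first principal component, which held 37.5% of the variance, group accounted for 99.0% of the spread of the arrays and slide for 0.1%. On the second, with 19.4%, the shares were 98.0% and 0.2%. Fed LKO replicate 3 stood apart on the third component, at 57.5 against -16.6 to -4.2 in the other fed LKO mice, and the mean of its acute phase genes was 1.52 against -0.16 to 0.25, with Cxcl1, a neutrophil-attracting chemokine, at 5.13 against 0.62 to 1.16. The counts of every comparison are therefore also given without that animal.

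**Figure D1:**
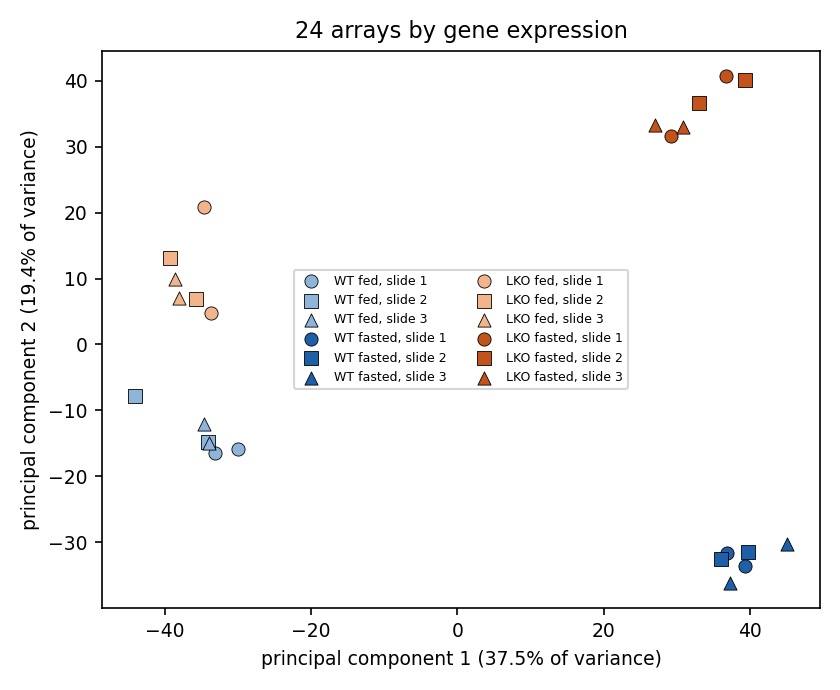
Each point is 1 of the 24 arrays, placed by its first and second principal components of log2 gene levels, with percent of variance on the axes, colour for the group and shape for the slide. The 4 groups lie apart from each other on every slide.

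Ppara itself was read by 2 probes on chromosome 15 (mm9, 85632110 to 85632169 and 85637193 to 85637252). At the first, its level was 5.27 ± 0.20 (SD, n = 5) in fed WT, 4.61 ± 0.37 (n = 6) in fed LKO, 5.90 ± 0.13 (n = 5) in fasted WT and 5.04 ± 0.12 (n = 6) in fasted LKO. It was thus 1.58-fold lower in fed LKO (log2 -0.66, SE 0.14, adjusted p = 0.0066) and 1.82-fold lower in fasted LKO (log2 -0.86, SE 0.14, adjusted p = 5.25e-05). At the other probe it was 1.79-fold and 1.99-fold lower. The labels do not say which part of the gene is deleted, and a probe outside the deleted part checks nothing. The genotype difference in Ppara did not pass a test of change with fasting (log2 -0.20, SE 0.19, adjusted p = 0.528).

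**Figure D2:**
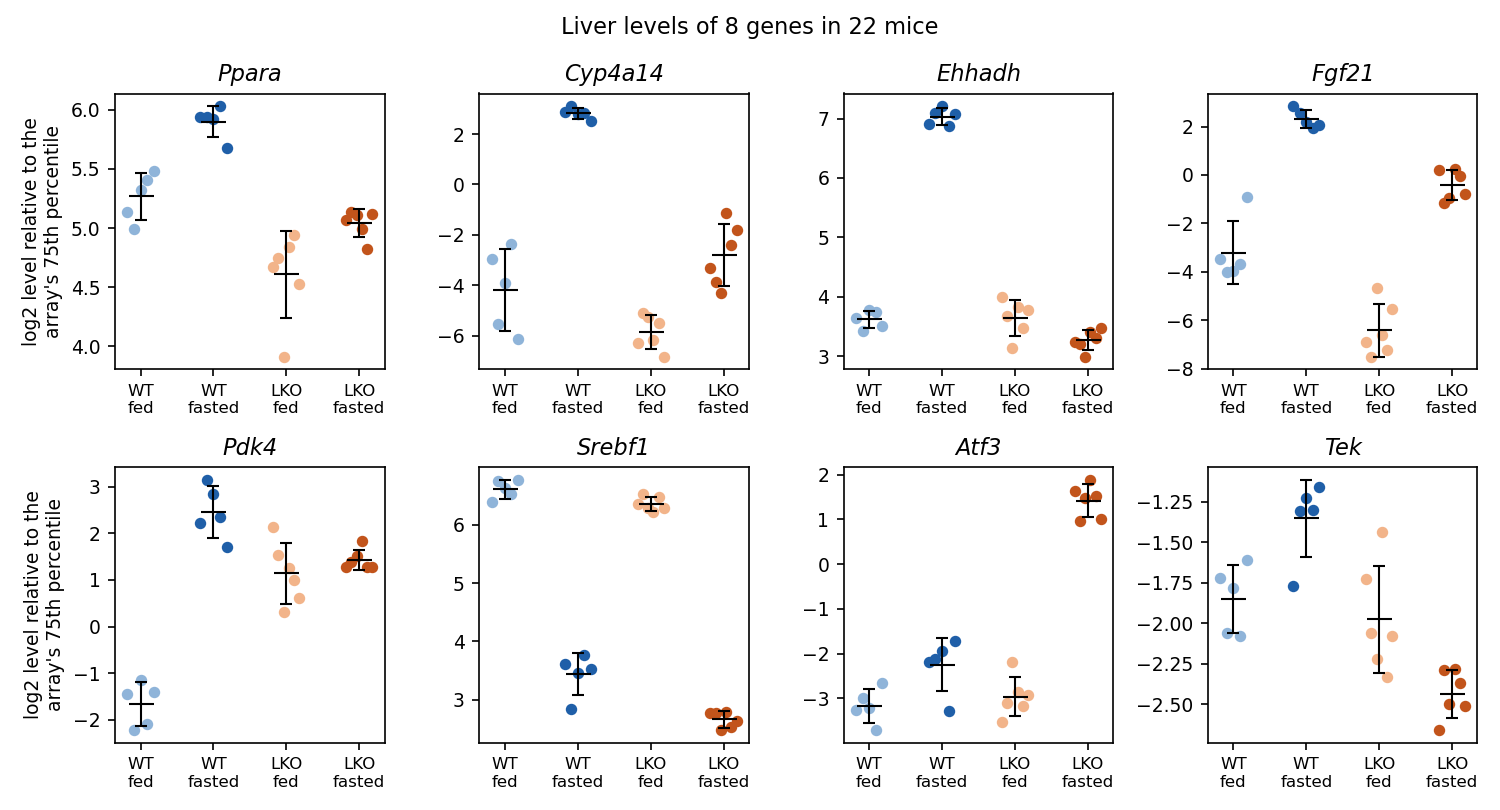
Each panel shows 1 gene, with a point per animal (5 fed WT, 5 fasted WT, 6 fed LKO, 6 fasted LKO), a horizontal mark at the group mean and bars for 1 SD. The vertical axis is the log2 level relative to the array's 75th percentile. Ehhadh was at 7.03 in fasted WT and between 3.27 and 3.64 on average in the other groups, and Pdk4 was at -1.67 in fed WT and between 1.14 and 2.46 on average in the others.

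The first question was how the WT liver responds to a 24 h fast. Genes of fatty acid oxidation and lipid storage were among those with the largest rises. Cyp4a14 and Cyp4a10, microsomal enzymes of fatty acid omega-oxidation, rose by 7.01 (SE 0.64, n = 5 and 5) and 5.71 (SE 0.57), the first from a fed level well above background in 3 of 5 mice. Fgf21, which encodes a liver hormone of fasting, rose 46.1-fold (log2 5.53, SE 0.56), and Cidec, a lipid droplet protein, rose 39.9-fold (log2 5.32, SE 0.29). Thrsp, a gene of lipogenesis, fell 22.7-fold (log2 -4.50, SE 0.28). The probes of Cyp4a14, Fgf21 and Ehhadh lie on chromosomes 4, 7 and 16 of mm9, starting at 115168609, 52869305 and 21761914.

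All 20 measured genes of mitochondrial beta-oxidation rose in fasted WT mice, with a median of 0.89. They include Cpt1a, the carnitine transferase that admits fatty acids to mitochondria (log2 1.54, SE 0.10), and Crat (log2 2.24, SE 0.17). The list's camera test gave adjusted p = 0.104 with an estimated correlation, and 20 members passed when adjusted over the list alone. Of 21 peroxisomal genes, 18 rose and 1 fell (19 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, rose 10.6-fold (log2 3.41, SE 0.13), and Acot3 rose 16.9-fold (log2 4.08, SE 0.52). Of 33 genes of fatty acid uptake and lipid droplets, 19 rose and 3 fell (23 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation). Acot2, G0s2, an inhibitor of adipose triglyceride lipase, Cd36, a fatty acid transporter, and Plin2, a lipid droplet coat protein, rose by 3.95, 3.59, 1.97 and 1.88. The omega-oxidation list had 6 members higher and 1 lower of 10 (8 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation). Among 9 ketone body genes, 5 rose and 4 fell (9 adjusted over the list alone, adjusted p = 0.934 with an estimated correlation). The ketone body list's median of 0.39 and its mean of -0.29 differ in sign. Vnn1, a pantetheinase, rose 6.47-fold (log2 2.69, SE 0.47).

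Gluconeogenic genes rose in 11 of 17 cases and fell in 1 (12 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation). Pdk4, a kinase that shuts off pyruvate oxidation, rose 17.5-fold (log2 4.13, SE 0.30), Got1 rose 4.92-fold (log2 2.30, SE 0.19), and Pck1, the gatekeeper of gluconeogenesis, rose 1.95-fold (log2 0.96, SE 0.12). Of 28 genes of amino acid catabolism and the urea cycle, 21 rose and 2 fell (25 adjusted over the list alone, adjusted p = 0.223 with an estimated correlation), among them Oat (log2 1.41) and Cth (log2 1.36). In the same livers 20 of 23 genes of fatty acid synthesis fell and 2 rose (22 adjusted over the list alone, adjusted p = 0.206 with an estimated correlation). The lipogenic transcription factor gene Srebf1 fell by 3.17 (SE 0.13), Scd1, a desaturase, by 2.89 (SE 0.37), and Fasn, fatty acid synthase, by 2.85 (SE 0.27). Pnpla3 was at least 13.7-fold lower, since no fasted WT mouse was well above background. That bound was 8.70-fold without fed WT replicate 5 and 24.8-fold without fed WT replicate 4. Of 25 genes of cholesterol synthesis and uptake, 18 fell and 1 rose (19 adjusted over the list alone, adjusted p = 0.352 with an estimated correlation). Unfolded protein response genes fell in 17 of 20 cases (18 adjusted over the list alone, adjusted p = 0.356 with an estimated correlation), for example Sdf2l1 (log2 -1.99). Cell cycle genes fell in 18 of 21 cases (18 adjusted over the list alone, adjusted p = 0.223 with an estimated correlation), for example Mcm5, a part of the replicative helicase (log2 -2.34). Hsd3b5, a male-biased steroid enzyme gene, fell 47.0-fold, and Bhlha15 was at least 15.8-fold lower. Endothelial markers changed in the same livers: 8 of 13 rose and none fell (8 adjusted over the list alone, adjusted p = 0.543 with an estimated correlation), with Lyve1 3.12-fold higher. Other cell type markers passed too, with 4 lower of 7 neutrophil and monocyte, 3 lower of 7 red blood cell, 1 higher and 4 lower of 11 lymphocyte, 6 higher and 4 lower of 15 stellate and 1 higher and 3 lower of 12 macrophage markers (5, 3, 5, 11 and 4 adjusted over the list alone, adjusted p = 0.223, 0.662, 0.830, 0.937 and 0.860 with an estimated correlation). So did 3 higher and 4 lower of 15 hepatocyte, 2 higher and 2 lower of 6 pancreas, 2 higher and 1 lower of 7 adipocyte and 2 lower of 10 cholangiocyte markers (7, 4, 3 and 1 adjusted over the list alone, adjusted p = 0.937, 0.779, 0.841 and 0.841 with an estimated correlation). Over all genes 7639 of 17203 passed, so such counts alone do not set a list apart. Normexp background correction, whose offset pulls dim signals together, gave 5.19 for Cyp4a14, 4.36 for Fgf21, -2.30 for Bhlha15, -2.38 for Pnpla3 and -1.46 for Mcm5, and averaging the probes of a gene gave 4.76 for Acot3.

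In all, 3891 genes rose and 3748 fell with fasting in WT, of 17203 tested, and 640 and 553 of these changed at least 2-fold. The balance turned to 3794 higher and 3937 lower with quantile normalization. Fed and fasted animals did not overlap for 34.4% of genes, where chance gives 0.794%. With slide as a block 7430 genes were called, and without fed LKO replicate 3, which enters through the shared spread, 8122. Median changes of the mitochondrial list were 0.77, 0.86 and 1.02 within slides 1, 2 and 3, and those of the fatty acid synthesis list were -1.30, -1.88 and -2.30.

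The same fast in mice without hepatic Ppara was the next comparison. Fgf21 rose by 6.00 (SE 0.51, n = 6 and 6) in LKO, but only 1 of 6 fed LKO mice was well above background, and the rise was 2.72 with normexp background correction. Gdf15, a stress-induced cytokine, rose 28.7-fold (log2 4.84, SE 0.23), Atf3, a stress-induced transcription factor, 20.8-fold (log2 4.38, SE 0.25), Egr1, an immediate early gene, 19.5-fold (log2 4.28, SE 0.41), and Trib3 7.80-fold (log2 2.96, SE 0.22). Cidec rose 19.0-fold, Cyp4a10 rose 19.4-fold, and Cyp4a14 was at least 4.16-fold higher, since no fed LKO mouse was well above background. Thrsp fell 30.5-fold (log2 -4.93, SE 0.26) and Srebf1 fell 12.9-fold (log2 -3.69, SE 0.12).

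Oxidation genes were split in fasted LKO mice. Of the 20 mitochondrial genes, 7 rose, 3 fell and 10 did not pass (10 adjusted over the list alone, adjusted p = 0.840 with an estimated correlation). The median of this mitochondrial beta-oxidation list was -0.01, or 0.07 in the authors' deposited table, and its mean 0.18. Cpt1a rose 3.16-fold (log2 1.66, SE 0.09) and Acadl 2.26-fold (log2 1.17, SE 0.07). Of 21 peroxisomal genes, 5 rose and 9 fell (14 adjusted over the list alone, adjusted p = 0.880 with an estimated correlation). Ehhadh and Pecr had changes of -0.37 (SE 0.12) and -0.92 (SE 0.09). Fatty acid uptake and droplet genes gave 12 higher and 10 lower of 33 (24 adjusted over the list alone, adjusted p = 0.825 with an estimated correlation): Plin4 and Plin2 rose by 2.72 and 1.40, while Cd36 fell by 0.87. The omega-oxidation list had 5 higher and 4 lower of 10 (9 adjusted over the list alone, adjusted p = 0.840 with an estimated correlation), and the ketone body list 2 higher and 5 lower of 9 (9 adjusted over the list alone, adjusted p = 0.762 with an estimated correlation). Pdk4 was at 0.28 (SE 0.28, adjusted p = 0.427) and Vnn1 at -0.15 (SE 0.43, adjusted p = 0.801), so neither passed.

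Fatty acid synthesis genes fell in LKO in 19 of 23 cases and rose in 2 (21 adjusted over the list alone, adjusted p = 0.524 with an estimated correlation), with Fasn at -2.92 (SE 0.25) and Pnpla3 at -5.83 (SE 0.76, 2 of 6 fasted mice well above background). Cell cycle genes fell in 19 of 21 cases (19 adjusted over the list alone, adjusted p = 0.524 with an estimated correlation), including Mcm5 (log2 -2.14). Cholesterol genes fell in 13 of 25 cases and rose in 5 (18 adjusted over the list alone, adjusted p = 0.840 with an estimated correlation), with Fdps at -0.96 and Hmgcs1 at 0.88. Unfolded protein response genes gave 11 lower and 1 higher of 20 (12 adjusted over the list alone, adjusted p = 0.825 with an estimated correlation). Of 19 integrated stress response genes, 10 rose and 2 fell (12 adjusted over the list alone, adjusted p = 0.597 with an estimated correlation). Gluconeogenic genes gave 7 higher and 3 lower of 17 (10 adjusted over the list alone, adjusted p = 0.789 with an estimated correlation), with Pck1 1.92-fold higher (log2 0.94, SE 0.11), and amino acid genes 16 higher and 2 lower of 28 (18 adjusted over the list alone, adjusted p = 0.762 with an estimated correlation). Igfbp1, a fasting-induced binding protein, rose 9.07-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 12.4-fold (log2 -3.63, SE 0.40), the fatty acid binding protein gene Fabp5 30.0-fold, the glucose transporter gene Slc2a4 18.3-fold and the transcription factor gene Onecut1 15.7-fold. Endothelial markers gave 1 higher and 6 lower of 13 beside these groups (8 adjusted over the list alone, adjusted p = 0.840 with an estimated correlation), with Gpr182 at -0.60. Of the other cell type markers, 4 of 15 stellate were higher and 7 lower, 3 of 15 hepatocyte were higher and 6 lower, 1 of 11 lymphocyte was higher and 4 lower, and 3 of 7 neutrophil and monocyte were lower (12, 9, 5 and 3 adjusted over the list alone, adjusted p = 0.840, 0.853, 0.825 and 0.597 with an estimated correlation). Pancreas markers gave 3 higher and 2 lower of 6, adipocyte 2 lower of 7, red blood cell 2 lower of 7 and macrophage 1 higher and 2 lower of 12 (6, 1, 2 and 1 adjusted over the list alone, adjusted p = 0.840, 0.825, 0.825 and 0.853 with an estimated correlation). Over all genes 8560 of 17203 passed, so such counts alone do not set a list apart. With normexp correction the changes were 3.45 for Atf3, 3.56 for Egr1, 0.94 for Cyp4a14, -3.04 for Pnpla3, -1.18 for Mcm5 and -2.77 for Slc2a4. With probes averaged, Gpr182 was at -0.39 and Onecut1 at -3.32.

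In LKO 3935 genes rose and 4625 fell, 579 and 613 of them at least 2-fold. Fed and fasted LKO animals did not overlap for 27.3% of genes, where chance gives 0.216%. The count was 8336 with slide as a block and 8760 without fed LKO replicate 3. Within slides 1, 2 and 3 the median of the mitochondrial list was 0.07, -0.04 and -0.01, and that of the fatty acid synthesis list -1.95, -1.94 and -1.63.

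Across the 17203 genes the fasting changes of LKO and WT had a Pearson correlation of 0.692, with no animal in common, and genes are not independent replicates. Both genotypes called 5185 genes, 4868 of them in the same direction. Among these, 2320 rose in both, where 890 were expected with independent calls, and 2548 fell in both, where 1008 were expected. The other 317 moved in opposite directions.

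The third comparison asked what the loss of hepatic Ppara does in fed mice. Vnn1 was 37.2-fold lower in fed LKO than in fed WT (log2 -5.22, SE 0.45, n = 6 and 5), with 5 of 6 fed LKO mice well above background. Mfsd2a, a lysophospholipid transporter, was 23.3-fold lower (log2 -4.54, SE 0.41), Serinc2 14.9-fold lower (log2 -3.90, SE 0.18) and Cyp4a10 11.5-fold lower (log2 -3.53, SE 0.55). Gldn, which encodes a cell adhesion protein, was 36.7-fold higher (log2 5.20, SE 0.48), from a level well above background in 1 of 5 WT mice, and Tmeff2 was 8.02-fold higher (log2 3.00, SE 0.45) from 2 of 5. Serpinb1c was at least 2.61-fold higher, and Pdk4 was 7.02-fold higher (log2 2.81, SE 0.29).

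Fed LKO mice had lower levels of 15 of the 20 mitochondrial beta-oxidation genes, and none was higher (16 adjusted over the list alone, adjusted p = 0.0281 with an estimated correlation). The carnitine carrier gene Slc25a20 had a difference of -1.72 (SE 0.10), Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, -1.25 (SE 0.09), and Acadvl, the very long chain dehydrogenase, -1.04 (SE 0.06). Of 21 peroxisomal genes, 9 were lower and none higher (12 lower and 1 higher adjusted over the list alone, adjusted p = 0.083 with an estimated correlation), with Eci2 at -1.49 (SE 0.07) and Ech1 at -1.28 (SE 0.10). Ehhadh was at 0.02 (SE 0.12, adjusted p = 0.958). Omega-oxidation genes were lower in 3 of 10 cases (5 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation). Of 9 ketone body genes, 2 were higher and 3 lower (7 adjusted over the list alone, adjusted p = 0.948 with an estimated correlation). Cpt1a passed narrowly at -0.36 (SE 0.10, adjusted p = 0.0397). It no longer passed without fed WT replicate 1 (-0.36, adjusted p = 0.09), 3 (-0.34, 0.105) or 4 (-0.30, 0.113), or without fed LKO replicate 1 (-0.35, 0.0688), 2 (-0.35, 0.0796), 4 (-0.37, 0.0623), 5 (-0.34, 0.0861) or 6 (-0.36, 0.0668), with 0.0142 to 0.12 over all alternatives. Cpt1a also lost its call with replicate number as a block (-0.35, limma adjusted p = 0.12) and without a filter on dim probes (-0.36, 0.0809). Of 33 genes of fatty acid uptake and droplets, 1 was higher, G0s2 (log2 1.87, SE 0.37), and 6 were lower, such as Fitm1, a lipid droplet membrane protein (log2 -2.37, SE 0.34). Adjusted over the list alone, 5 were higher and 7 lower (adjusted p = 0.803 in camera with an estimated correlation). The sterol exporter genes Abcg8 and Abcg5 had differences of -1.06 (SE 0.11) and -0.80 (SE 0.08), and the complement factor gene Cfd one of -3.20 (SE 0.52, 2 of 6 fed LKO mice well above background). Cfd is also on the adipocyte marker list, where 1 of 7 members was lower and none higher (1 adjusted over the list alone, adjusted p = 0.251 in camera with an estimated correlation).

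Fatty acid synthesis genes gave 1 higher and 1 lower of 23 in fed mice (2 adjusted over the list alone, adjusted p = 0.974 with an estimated correlation), with Fasn at 0.11 (SE 0.26, adjusted p = 0.894). In limma 0 of 25 cholesterol, 0 of 20 unfolded protein response and 0 of 13 endothelial list members passed, also when adjusted over the list alone, while 6, 2 and 1 had an unadjusted p below 0.05, and their camera adjusted p values with an estimated correlation were 0.803, 0.974 and 0.986. Fgf21 was lower, by a log2 difference of -3.21 (SE 0.53, adjusted p = 0.00079), but 1 of 6 fed LKO mice was well above background and the size depended on the processing. It was -1.43 in the authors' deposited table, -1.47 with unsubtracted median signals, and -0.92 with normexp correction, where it did not pass (adjusted p = 0.0751, with 0.000133 to 0.0751 over all alternatives). Normexp correction also gave smaller differences of -3.51 for Vnn1, -2.93 for Serinc2, 2.47 for Gldn, 1.30 for Tmeff2, 0.75 for Serpinb1c and -1.51 for Cfd.

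When fed, 339 genes were higher and 342 lower in LKO, 75 and 89 of them at least 2-fold. The balance was 316 higher and 410 lower with quantile normalization, 291 and 381 in the authors' deposited table, and 472 and 411 without fed LKO replicate 3. The groups did not overlap for 3.7% of genes, where chance gives 0.433%. The count of 681 became 666 with slide as a block, 883 without fed LKO replicate 3, 374 when only the fed groups entered the fit and 1075 with array weights, which gave that animal a weight of 0.23. Within slides 1, 2 and 3 the median of the mitochondrial list was -0.64, -0.42 and -0.36.

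The same contrast was then made in fasted mice. Vnn1 was 267-fold lower in fasted LKO than in fasted WT (log2 -8.06, SE 0.45, n = 6 and 5; 5 of 6 LKO mice well above background), Serinc2 53.8-fold lower (log2 -5.75, SE 0.18), Cyp4a14 49.4-fold lower (log2 -5.63, SE 0.61) and Cyp4a10 31.1-fold lower (log2 -4.96, SE 0.55). The nuclear receptor gene Esrrg was at least 11.4-fold lower. Gldn was 58.6-fold higher (log2 5.87, SE 0.48; 2 of 5 WT mice well above background), Tmeff2 at least 5.76-fold higher, Atf3 12.7-fold higher (log2 3.66, SE 0.26), Blnk 10.5-fold higher (log2 3.39, SE 0.20) and Gdf15 10.4-fold higher (log2 3.38, SE 0.24).

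Peroxisomal genes were lower in fasted LKO in 20 of 21 cases and mitochondrial genes in 19 of 20, with none higher (21 and 20 adjusted over the list alone, adjusted p = 0.0242 each with an estimated correlation). Ehhadh was 13.5-fold lower (log2 -3.76, SE 0.12), Acot3 11.6-fold (log2 -3.53, SE 0.49), Slc25a20 5.67-fold (log2 -2.50, SE 0.10), Etfdh 5.32-fold (log2 -2.41, SE 0.09) and Cpt2 3.98-fold (log2 -1.99, SE 0.09). Of 33 genes of fatty acid uptake and droplets, 22 were lower and 2 higher (24 adjusted over the list alone, adjusted p = 0.0242 with an estimated correlation), for example Fitm1 (log2 -3.42, SE 0.34), G0s2 (log2 -2.65, SE 0.37) and Cd36 (log2 -2.24, SE 0.19). Of 7 adipocyte markers, 3 were lower and none higher (3 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation). The adipocyte list has members in common with the uptake and droplet list, and 6520 of all 17203 genes passed in this comparison. Omega-oxidation genes gave 7 lower and 1 higher of 10 (8 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation). Ketone body genes gave 5 lower and 2 higher of 9 (7 adjusted over the list alone, adjusted p = 0.485 with an estimated correlation). Cpt1a did not pass at -0.25 (SE 0.10, adjusted p = 0.054), but did without fasted LKO replicate 1 (-0.29, adjusted p = 0.0286) or 5 (-0.30, 0.023), without fed WT replicate 4 (-0.25, 0.044) and without fed LKO replicate 3 (-0.25, 0.0399), with 0.023 to 0.192 over all alternatives. It also passed with normexp correction (-0.25, limma adjusted p = 0.0402) and with genes well above background in all animals (-0.25, 0.0457). Gluconeogenic genes were lower in 9 of 17 cases (9 adjusted over the list alone, adjusted p = 0.228 with an estimated correlation), and Pck1 was at -0.13 (SE 0.11, adjusted p = 0.38). Fgf21 was 6.65-fold lower (log2 -2.73, SE 0.53) and Cyp7a1 6.14-fold lower (log2 -2.62, SE 0.42).

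Cholesterol genes were higher in fasted LKO in 18 of 25 cases and lower in none (19 higher and 1 lower adjusted over the list alone, adjusted p = 0.376 with an estimated correlation). Fdps was 2.96-fold higher (log2 1.57, SE 0.25). Unfolded protein response genes were higher in 9 of 20 cases (9 adjusted over the list alone, adjusted p = 0.601 with an estimated correlation). Of 19 integrated stress response genes, 9 were higher and 3 lower (12 adjusted over the list alone, adjusted p = 0.376 with an estimated correlation), with Nupr1 at 2.63 (SE 0.49) and Mthfd2 at 2.37 (SE 0.39, 3 of 5 fasted WT mice well above background). Acute phase and inflammation genes were higher in 8 of 27 cases and lower in none (8 adjusted over the list alone, adjusted p = 0.601 with an estimated correlation), with the chemokine genes Cxcl1 at 2.92 (SE 0.58) and Ccl2 at 1.82 (SE 0.26). Fatty acid synthesis genes gave 4 higher and 6 lower of 23 (11 adjusted over the list alone, adjusted p = 0.958 with an estimated correlation), and Fasn was at 0.03 (SE 0.26, adjusted p = 0.938). Hsd3b5 was 5.66-fold higher. Endothelial markers moved beside all these groups: 12 of 13 were lower and none higher (13 adjusted over the list alone, adjusted p = 0.376 with an estimated correlation), such as the receptor genes Tek (log2 -1.08, SE 0.14) and Clec4g (log2 -0.94, SE 0.13). Normexp correction gave -6.25 for Vnn1, -4.74 for Serinc2, -4.69 for Cyp4a14, -2.80 for Fitm1, -1.94 for Esrrg, 3.09 for Gldn, 1.39 for Tmeff2, 1.20 for Mthfd2 and 1.15 for Ccl2, and averaging the probes of a gene gave 1.34 for Nupr1.

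When fasted, 3086 genes were higher and 3434 lower in LKO, 404 and 425 of them at least 2-fold. With quantile normalization the balance turned, to 3405 higher and 3204 lower. The groups did not overlap for 25.3% of genes, where chance gives 0.433%, and 6292 genes were called with slide as a block and 7022 without fed LKO replicate 3. The median of the peroxisomal list was -1.32, -1.42 and -1.57 within slides 1, 2 and 3, and that of the endothelial list -0.57, -0.48 and -0.55. Across genes, which are not independent replicates, the LKO difference when fed and when fasted correlated at 0.482. Both feeding states called 512 genes: 279 lower in both (68.3 expected with independent calls), 200 higher in both (60.8 expected) and 33 in opposite directions.

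**Figure D3:**
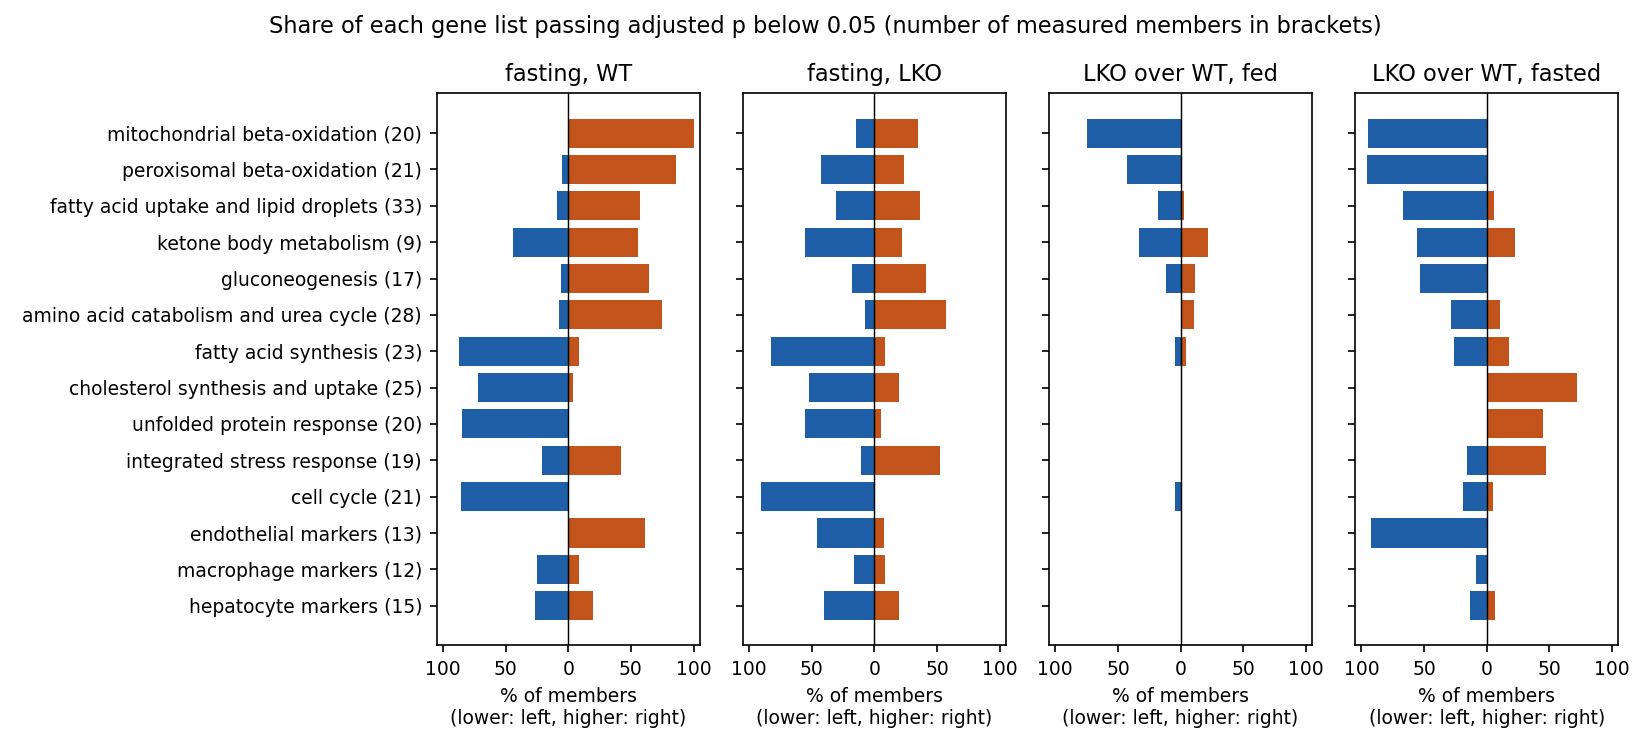
Bars show the percent of each gene list's measured members (number in brackets) with an adjusted p below 0.05, lower to the left and higher to the right, for 4 comparisons. All 20 mitochondrial genes were higher in fasted WT, 7 in fasted LKO, and 12 of 13 endothelial markers were lower in fasted LKO than in fasted WT.

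The last comparison tested whether the fasting response itself depends on hepatic Ppara. Responses were lower in LKO for G0s2 by a log2 difference of -4.52 (SE 0.53, all 22 animals), Acot3 by -4.23 (SE 0.70), Pdk4 by -3.85 (SE 0.41), Ehhadh by -3.78 (SE 0.17), Krt23, a keratin gene, by -3.66 (SE 0.33) and Cd36 by -2.84 (SE 0.27). Pdk4 and G0s2 were already higher in fed LKO than in fed WT, so part of their difference lies in the fed state. Ehhadh did not differ between the genotypes when fed by the same test. Responses were higher for Atf3 (3.45, SE 0.37), Gdf15 (2.92, SE 0.34), Hsd3b5 (2.85, SE 0.41) and Relb, an NF-kappaB subunit (2.76, SE 0.19).

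Peroxisomal genes had a lower response in LKO in 19 of 21 cases and droplet and uptake genes in 16 of 33, with none and 1 higher (20 and 19 adjusted over the list alone, adjusted p = 0.041 each with an estimated correlation). Neither list passed with genes well above background in all animals (adjusted p = 0.069 each), with probes averaged (0.0526 each) or with replicate number as a block (0.07 and 0.0796), and the ranges over all alternatives were 2.16e-17 to 0.07 and 2.07e-07 to 0.0796. Of 7 adipocyte markers, a list with members in common with the uptake and droplet list, 2 had a lower response (2 adjusted over the list alone, adjusted p = 0.508 with an estimated correlation). Acot2 had a difference of -2.91 (SE 0.27). Mitochondrial genes had a lower response in 18 of 20 cases (18 adjusted over the list alone, adjusted p = 0.0883 with an estimated correlation), such as Crat (-1.79, SE 0.23), Eci1 (-1.27, SE 0.12) and Etfdh (-1.16, SE 0.13). Omega-oxidation genes gave 5 lower and 1 higher of 10 (6 adjusted over the list alone, adjusted p = 0.508 with an estimated correlation), and Cyp4a14 is given no size here, since no fed LKO mouse was well above background. Gluconeogenic genes gave 7 lower of 17 (7 adjusted over the list alone, adjusted p = 0.274 with an estimated correlation) and amino acid genes 9 lower of 28 (10 adjusted over the list alone, adjusted p = 0.508 with an estimated correlation), of which 5 lower and 1 higher passed with unsubtracted median signals. Cyp7a1 and Vnn1 had differences of -2.89 (SE 0.60) and -2.84 (SE 0.63).

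Cholesterol genes had a higher response in LKO in 9 of 25 cases and a lower one in 1 (16 adjusted over the list alone, adjusted p = 0.508 with an estimated correlation). Integrated stress response genes gave 6 higher and 2 lower of 19 (10 adjusted over the list alone, adjusted p = 0.508 with an estimated correlation), with Mthfd2 at 2.66 (SE 0.55), and Ccl2 was at 1.85 (SE 0.36). Endothelial markers had a lower response in 9 of 13 cases and a higher one in none (13 adjusted over the list alone, adjusted p = 0.473 with an estimated correlation), with Tek at -0.95 (SE 0.20) and Clec4g at -0.94 (SE 0.18). Normexp correction gave 1.32 for Mthfd2 and 1.18 for Ccl2, and averaging probes gave -4.90 for Acot3 and 2.07 for Relb.

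Several fasting genes did not pass this test: Cpt1a at 0.12 (SE 0.14, adjusted p = 0.623), Pck1 at -0.02 (SE 0.16, adjusted p = 0.944), Fasn at -0.08 (SE 0.37, adjusted p = 0.92) and Cyp4a10 at -1.43 (SE 0.77, adjusted p = 0.215; -2.06 with probes averaged). Fgf21 was at 0.47 (SE 0.75, adjusted p = 0.726), but at -1.63 with normexp correction (adjusted p = 0.00652, with 0.00652 to 0.935 over all alternatives). It was also below 0, without passing, in the authors' deposited table (-1.21), with unsubtracted median signals (-1.17) and without fed WT replicate 5 (-0.10).

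The fasting responses of 3187 genes differed, 1326 with a higher and 1861 with a lower response in LKO, 251 and 299 of them by at least 2-fold. The excess of lower responses depended on the scaling, with 1642 higher and 1569 lower after quantile normalization and 1512 and 1479 in the authors' deposited table. Blocking by slide gave 3009 genes and leaving out fed LKO replicate 3 gave 4004. The median of the peroxisomal list was -0.69, -0.89 and -0.97 within slides 1, 2 and 3, and that of the endothelial list -0.65, -0.50 and -0.56.

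**Figure D4:**
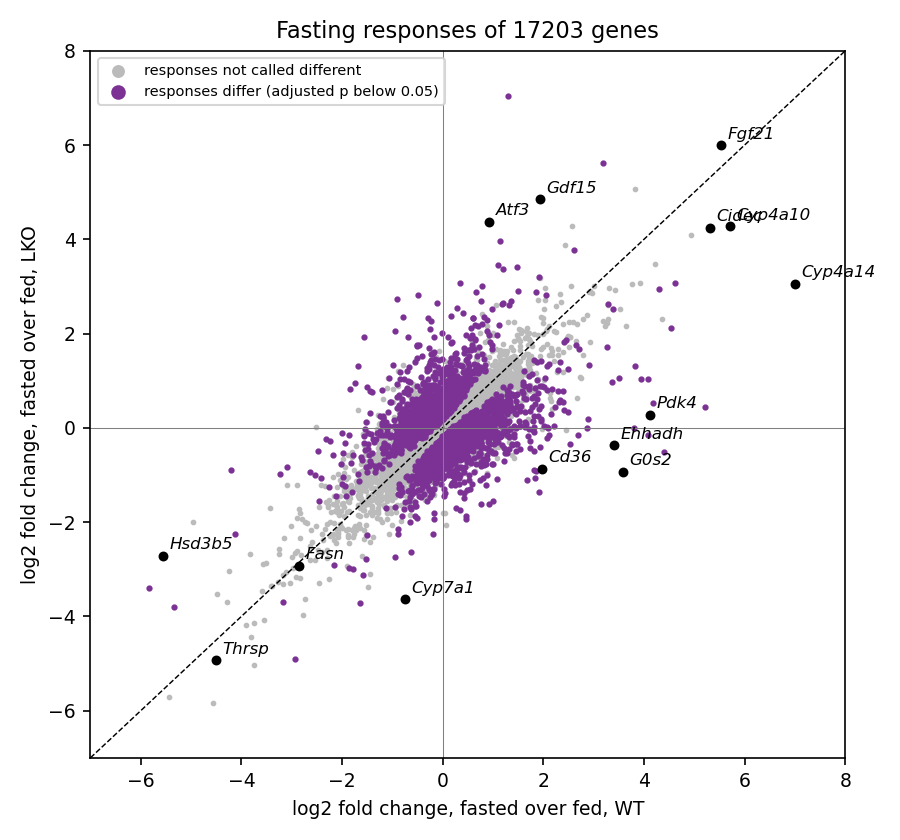
Each point is 1 of 17203 genes, with its log2 change on fasting in WT on the horizontal axis and in LKO on the vertical axis. The dashed line marks equal changes, and purple points are the 3187 genes whose responses differed at an adjusted p below 0.05. Ehhadh, Pdk4 and G0s2 lie far to the right near or below 0 on the vertical axis, while Atf3 and Gdf15 lie well above the line.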

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

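The tests of a slide effect, of immune cells and of the hepatocyte share below were chosen after the results were seen. In each group of 5 or 6 animals, the highest or lowest value was compared with the rest for every named gene and for 11 measures such as list means. An animal stood apart in 37 of 396 gene and group combinations and in 3 of 44 for the measures. Chance gives about 1 in 20, that is 19.8 and 2.2.

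Fed LKO replicate 3 accounted for 16 of these. It was high for Cxcl1 (5.13), Nupr1 (2.22), Mthfd2 (-1.16 against at most -3.24), Relb (-1.32), Plin2 (5.64), Crat (2.80), Lbp (4.08) and Ctsl (7.52), and low for Vnn1 (-5.82), Hsd3b5 (3.83), Slco1a1 (3.19), Cyp2a4 (7.79), Cyp1a2 (3.21), Eci1 (4.99) and Fitm1 (-2.95). Its score on principal component 3 was 57.5. Fasted LKO replicate 5 was low for Fdps (4.68) and high for Lyve1 (-0.42) and Bhlha15 (-2.15). Fasted WT replicate 1 was low for Gpr182 (2.69), Tek (-1.77), the endothelial list mean (0.09) and the macrophage list mean (-0.60). Fed WT replicate 5 was high for Fgf21 (-0.90) and Abcg5 (5.05) and low for Sdf2l1 (2.33) and Igfals (1.73). Fed LKO replicate 1 was high for Esrrg (-4.85), Serinc2 (-2.62) and Dbp (3.72), and fed WT replicate 2 was high for Egr1 (0.20) and low for Pck1 (7.19) and Per2 (2.92). Single values apart were those of Nr0b2 in fasted LKO replicate 2 (1.56), Igfals in fasted LKO replicate 3 (0.32), Etfdh in fasted LKO replicate 4 (3.78), Blnk in fasted LKO replicate 6 (1.74), Cyp4a10 in fed LKO replicate 5 (-1.72), Igfbp2 in fasted WT replicate 2 (7.56) and Bhlha15 in fasted WT replicate 4 (-6.02). No fasted WT mouse was well above background for Bhlha15, so that last value is not a measured level. Not every fed LKO mouse was well above background for Vnn1, so the low Vnn1 value of fed LKO replicate 3 may not be one either.

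The interaction test found fasting responses that differed between LKO and WT for 23 of the named genes with an interaction value in this text. Named genes without such a value were not counted. Lower responses in LKO were -4.52 for G0s2, -4.23 for Acot3, -3.85 for Pdk4, -3.78 for Ehhadh, -3.66 for Krt23, -2.91 for Acot2, -2.89 for Cyp7a1, -2.84 for Cd36, -2.84 for Vnn1, -1.79 for Crat, -1.27 for Eci1, -1.16 for Etfdh, -0.95 for Tek and -0.94 for Clec4g. Higher responses were 3.45 for Atf3, 2.92 for Gdf15, 2.85 for Hsd3b5, 2.76 for Relb, 2.66 for Mthfd2 and 1.85 for Ccl2. For 3 genes a group had no mouse well above background at the probe, so that the printed size is not a measured one: -3.95 for Cyp4a14 (fed LKO), -2.90 for Abcd2 (both LKO groups, -0.86 with normexp correction) and 3.48 for S100g (fasted WT and fed LKO, 0.69 with normexp correction).

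LKO and WT differed in 1 direction in both feeding states for 479 genes. A stretch of another strain's chromosome around Ppara is argued against as the main source, since 2.31% of these genes lay within 10 Mb of Ppara, against 1.74% of all genes tested (11 genes where 8.27 were expected, Fisher's exact test, two-sided p = 0.288). A slide effect is argued against by the layout, since each slide held 2 arrays of every group. Such genes were also picked without the animals of a slide. On that slide, 95.1% of them (560 of 589 cases over the 3 slides) had the sign seen in the other animals, in both feeding states. For the genes not picked, 46% had the sign seen in the other animals in both feeding states. A difference that follows the genotype itself may then account for most of these genes, as a hypothesis found and tested on the same data.

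Of 19 integrated stress response genes, 9, among them Atf3, were higher in fasted LKO than in fasted WT and 3 were lower. That list did not pass camera with an estimated correlation (adjusted p = 0.376). Immune cells in the tissue are argued against, since only 1 of 19 macrophage, neutrophil and monocyte markers was higher, and their median difference was 0.07 (SD 0.27). Handling of the tissue before freezing stays open, because 14 of 24 measured immediate early genes were higher in fasted LKO and 1 was lower, with a median of 0.75, which handling that differed between the groups could give. A stress response of the fasted liver without Ppara could raise the same genes and was not tested apart from it.

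Of 13 endothelial markers, 9 had a lower fasting response in LKO than in WT, but the list did not pass camera with an estimated correlation (adjusted p = 0.473). A different share of hepatocytes is argued against, since it would move the markers of all other cell types alike, while the endothelial list mean lay below the macrophage list mean in the interaction by a log2 difference of -0.60 (SE 0.20), below the lymphocyte mean by -0.61 (SE 0.15) and below the cholangiocyte mean by -0.80 (SE 0.28). The stellate list mean moved the same way as the endothelial one (-0.26, SE 0.13), and their difference of -0.38 (SE 0.19) lay at about 2 SE, so a shift shared by these cell types stays open. The scaling between arrays is argued against too, as at least 8 of 13 markers passed with a lower response under every other scaling tried. A change in endothelial cells or in their transcripts that depends on genotype and feeding stays open, as a hypothesis.

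For each of the 5 gene counts, 100 splits of the animals into groups of the same sizes were counted, the real one included. Only 1 of 100, the real split, gave as many genes in each comparison, the lowest share that 100 splits can show. Other splits mix animals of the real groups, so a real difference widens the spread within groups and lowers their counts. The interaction splits moved genotype labels within each feeding state. They test for any genotype difference, so no conclusion is drawn for the interaction alone. For fasting and genotype the counts argue against chance without excluding it, with the narrowest margin for genotype when fed. The real and the highest other counts were 7639 and 1423 for fasting in WT, 8560 and 4814 for fasting in LKO, 681 and 597 for genotype when fed, 6520 and 4859 for genotype when fasted, and 3187 and 840 for the interaction.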

How the results depend on the processing

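All alternatives were planned before the data were examined. Gene counts are given in the order fasting in WT, fasting in LKO, genotype when fed, genotype when fasted and interaction, where 7639, 8560, 681, 6520 and 3187 genes were called. Counting probes in place of genes gave 11591, 13075, 1072 and 10287 for the first 4, with 28111 probes tested in place of 17203 genes. With the 8 arrays of a single slide the counts were 948, 1635, 3, 459 and 0 on slide 1, where limma gave 1873 interaction genes at an unadjusted p below 0.05, then 3507, 4140, 13, 2176 and 115 on slide 2, and 4536, 4550, 118, 2429 and 648 on slide 3. These use 2 arrays per group, and slide 1 held fed LKO replicate 3. Genotype when fed gave 374 genes with only the fed groups in the fit and 1075 with array weights, and the cause was not tested. An adjusted p below 0.01 left 328 genes for genotype when fed and 1537 for the interaction, and a change of at least 2-fold left 1193, 1192, 164, 829 and 550. Leaving out each animal in turn gave 6995 to 8122, 8149 to 8760, 471 to 883, 5710 to 7022 and 2740 to 4004, with the highest count in every case without fed LKO replicate 3. All other counts stayed within 1.5 times. Quantile normalization moved the share of higher calls in the interaction by 9.5 points, the largest move under any scaling, and turned the balance from more lower to more higher calls. The correlation of the fasting responses was 0.725 over the 11010 genes called in either genotype.

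No clear pairing by replicate number was seen. Residuals of animals with the same number correlated across genes at -0.18 to 0.18, above 0.1 in 5 of 31 pairs, and genes are not independent replicates. The best match of an animal in another group carried its own number in 0 to 2 cases per pair of groups. Animals with different numbers were given no range to compare, so weak pairing is not excluded. A replicate block gave 7438, 8408, 548, 6167 and 2829 genes. Of 155 list tests, 6 passed with an estimated correlation, 14 without a filter on dim probes, 15 with slide as a block, 51 with a preset correlation of 0.01 and 73 with fry. The preset test differed from the reported one only in the correlation, which was estimated at 0.487 for the mitochondrial list, for example. The cause of the other moves was not tested. All 6 passed under each of these settings, and 4 of them when genes had to be well above background in all animals, when probes were averaged and with the replicate block. The lists lost there were those of peroxisomal genes and of uptake and droplet genes in the interaction. No list reversed. Of 5483 values of named genes under alternatives, 5424 kept their direction and side of the threshold, 25 lost a call and 6 gained one. Named genes were largely picked for large called changes, and many alternatives left out 1 animal, so this total says little about other genes. An earlier draft had dropped unstable genes from this total after their results were seen, and every gene reported here was put back. All lost calls were for genotype when fed: 10 for Cpt1a (-0.42 to -0.30), 7 for Arntl (0.60 to 0.95, adjusted p 0.0145 to 0.0716), 4 for Dbp (-1.05 to -0.67, adjusted p 0.0155 to 0.0675), 3 for Il1rn (0.65 to 2.50, adjusted p 0.00319 to 0.142) and 1 for Fgf21. Cpt1a, Arntl and Dbp lost calls mostly when 1 animal was left out, Il1rn under normexp, unsubtracted median signals with quantile normalization, and the authors' table. All 6 gained calls were for Cpt1a when fasted. The Fgf21 interaction reversed under normexp, to -1.63 with an adjusted p of 0.00652 (0.00652 to 0.935 over its alternatives). It was also below 0, without passing, in the authors' table (-1.21), with unsubtracted median signals (-1.17) and without fed WT replicate 5 (-0.10), and the cause was not tested. These last 3 are among 27 values that passed neither before nor after and changed sign. Genes near background are limited by depth: 52.2% to 60.6% of probes were well above background on an array.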

Other observations

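The values of single acute phase genes and of Cdpf1 below were chosen after the data were seen. Of 22 autophagy and lysosome genes, 11 rose with fasting and 2 fell in WT (14 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation), and 12 rose and 5 fell in LKO (17 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). Ctsl, a lysosomal protease, rose 1.87-fold and 2.22-fold, and in LKO the autophagy receptor gene Sqstm1 rose 2.76-fold and Gabarapl1 2.22-fold. Male-biased liver genes fell in 9 of 17 cases and rose in 1 in each genotype (10 adjusted over the list alone in each, adjusted p = 0.306 in WT and 0.762 in LKO, both with an estimated correlation), with Hsd3b5 6.54-fold lower in LKO. Female-biased genes rose in 6 of 14 cases in WT and 8 of 14 in LKO (6 and 8 adjusted over the list alone, adjusted p = 0.438 and 0.503 with an estimated correlation). Cyp17a1, on the same list, was 2.23-fold higher in fasted LKO than in fasted WT. Among 20 clock genes, 5 rose and 4 fell in WT, and 10 rose and 4 fell in LKO (9 and 14 adjusted over the list alone, adjusted p = 0.940 and 0.762 with an estimated correlation). Ciart rose 3.19-fold and 2.18-fold, and Nr1d1, a clock repressor, was 3.35-fold lower in fasted LKO than in fasted WT while Cry1 was 1.73-fold higher (log2 0.79, or 0.51 with normexp correction).

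Xenobiotic genes were higher in fasted LKO than in fasted WT in 12 of 27 cases and lower in 3 (17 adjusted over the list alone, adjusted p = 0.601 with an estimated correlation), with Cyp1a2 2.55-fold higher, and Cyp2c55 fell 5.75-fold with fasting in WT (log2 -2.52, or -1.72 with normexp correction). Bile acid genes rose in 7 and fell in 4 of 18 cases in fasted WT (11 adjusted over the list alone, adjusted p = 0.841 with an estimated correlation). Cyp8b1, which sets the cholic acid share, rose 5.61-fold and Abcb11, the bile salt export pump, fell 2.34-fold. Of 27 acute phase genes, 10 fell and 4 rose in fasted WT (16 adjusted over the list alone, adjusted p = 0.830 with an estimated correlation), with Saa2 8.51-fold lower, and in LKO 8 fell and 5 rose (13 adjusted over the list alone, adjusted p = 0.946 with an estimated correlation), with Cd14 3.16-fold higher. The LKO counts include fed LKO replicate 3, with a mean of acute phase genes of 1.52. That mean was -0.16 to 0.25 in the other fed and -0.08 to 0.33 in the fasted LKO mice. The list was not counted without that animal, so the LKO falls may rest on it. Growth hormone axis genes rose in 3 and fell in 2 of 16 cases in WT (5 adjusted over the list alone, adjusted p = 0.841 with an estimated correlation), with Igfbp2 2.54-fold higher. Secreted factors rose in 6 and fell in 5 of 17 cases in WT and rose in 7 and fell in 4 in LKO (11 and 12 adjusted over the list alone, adjusted p = 0.841 and 0.663 with an estimated correlation).

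Among the cell type lists, LKO against WT when fasted gave 1 higher and 2 lower of 15 hepatocyte markers, 1 lower of 12 macrophage, 1 lower of 15 stellate, 1 higher of 11 lymphocyte, 1 higher of 7 neutrophil and monocyte, 3 higher of 10 cholangiocyte, 2 higher of 6 pancreas and 2 higher of 7 red blood cell markers. Adjusted over the list alone, the counts were 2, 0, 0, 0, 1, 3, 2 and 2 in that order (limma gave an unadjusted p below 0.05 for 3, 4 and 3 of the macrophage, stellate and lymphocyte markers), and with limma's camera and an estimated correlation the adjusted p values were 0.958, 0.987, 0.843, 0.601, 0.719, 0.601, 0.601 and 0.630.

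In fed LKO replicate 3, Saa1, Saa2, Lcn2 and Orm2 were at 9.87, 10.22, 6.96 and 8.11, against highest values of 7.42, 7.76, 2.19 and 7.01 in the other fed LKO mice. The gene Cdpf1 has its probe beside the second Ppara probe, starting at 85637436 on chromosome 15, and had differences between LKO and WT of -0.63 when fed and -0.40 when fasted.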
